A study of Homo sapiens with 11 samples.

How the data were processed

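RNA of in vitro dendritic cells was sequenced in 11 libraries. Human CD34+ progenitors were cultured with cytokines, and the dendritic cells were then sorted, per the labels on CD141 and Clec9A for the conventional type 1 cells (cDC1) and on CD1c and FCERA for the type 2 cells (cDC2). The cDC1 came from cultures on a DLL1 feeder (3 libraries), on an OP9 feeder (3 libraries) or without feeder cells (3 libraries), and the cDC2 from cultures on an OP9 feeder (2 libraries). DLL1 is a ligand of Notch receptors and OP9 is a mouse stromal cell line. The labels say neither what the DLL1 feeder was made from nor whether a Notch ligand was added to the feeder-free cultures. Libraries were made by the authors with a stranded mRNA kit and read in pairs on a NovaSeq.

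The deposited count table holds expected counts per gene, estimated reads that are not all whole and are not scaled between libraries. The deposited TPM table holds TPM values, transcripts scaled by length, in which every library sums to the same total. The submitters name FastQC 0.11.8, Trim Galore 0.6.6, STAR 2.7.5b, Salmon 1.2.1, DESeq2 1.30.1 and the build hg38, and the annotation release is not given in the sources used here. The authors' normalized counts were not used here, because they equal the rounded counts divided by 1 factor per library, and those factors were set together with columns that match no sample. Each of the 2 tables used here has 6 columns that match no sample, and these were left out.

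Of the 60240 genes in the count table, 58020 were matched by identifier, without the version number, to GENCODE 29 on GRCh38 for position and gene type. Because the samples come from people, 486 genes that can point to a donor, which held 0.631% of the counts, were left out throughout. Where several genes had 1 symbol, which was so for 1142 genes, the best counted kept the plain symbol. Counts were rounded, scaled by the trimmed mean of M-values (TMM) and fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with group as the term and all 11 libraries in 1 fit. The edgeR filter on low counts kept 18537 genes. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over these genes. The standard error of a log2 fold change is its size divided by the square root of F. The common dispersion was 0.0823, a biological coefficient of variation of 28.7%. Levels are counts scaled to library size (CPM) with the SD between libraries.

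Where a group held no counts of a gene, the fold is given against a floor of 3 counts over the group, as a bound. Where it held 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals cover counting error only. A median over a list is also given with such genes at their bound wherever that changes it.

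A set of 29 gene lists was tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, and p-values were adjusted over the lists of a comparison. Camera asks whether the genes of a list moved more than the other genes. The test was repeated with a correlation estimated for each list, and with fry, which asks whether the genes of a list moved, on balance, in 1 direction. Beside the number of members called over all genes stands the number called when adjusted over the list alone. A further pair of sets held the 200 genes with the largest change to either side between cDC1 and cDC2, and was tested between DLL1-feeder and feeder-free cDC1, which share no library with the groups the sets came from.

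The groups, the 4 comparisons, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from what is described as added or singled out later. The rule names, per comparison, the 10 highest and the 10 lowest log2 fold changes among called genes with a gene symbol, a mean log2 CPM of at least 1 and every library of 1 group above every library of the other. It also allows up to 4 called members of each list with the largest changes. Whatever their result, it gives HES1, HES4, HEY1, NRARP, DTX1, CLEC9A, XCR1, THBD, CADM1, BATF3, IRF8, IRF4, CD1C, FCER1A, CLEC10A, FLT3, TLR3 and CCR7. HEY1 and DTX1 did not pass the filter, with 17 and 20 counts over all libraries.

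The alternatives were DESeq2 1.42.0, size factors by relative log expression, no filter or a stricter filter (CPM of at least 1 in 3 libraries), limma on log2 TPM with a pseudocount of 1 or 0.1 over genes with a TPM of at least 1 in 2 libraries, fits of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. A fit of protein-coding genes of the nuclear chromosomes alone, and a blocked fit of the DLL1-feeder and feeder-free libraries alone, were added after seeing the data. Replicate numbers come from the sample titles. Deviations from the group means correlated between DLL1-feeder and feeder-free libraries of the same number, over genes, at 0.38, 0.39 and 0.31, so the numbers were taken to pair these groups. The fit fixed beforehand has no block and is the one reported, and the blocked value is given beside a result between these groups where it changes the call. The other groups were not taken to be paired by number, though OP9-feeder replicates 1 and 2 correlated best with numbers 2 and 1 of these groups.

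The method was tested on simulated data with the dispersion and depths of these libraries, with 100 genes changed at each fold. The changed genes were drawn from those with a mean CPM of at least 1, so the recovery at lower levels was not measured. It recovered 53% to 64% of 2-fold changes in the comparisons of 3 libraries with 3, and 49% with 2 cDC2 libraries. It recovered 88% to 91% of 4-fold changes in the former and 85% in the latter, with 6 to 12 unchanged genes called. Nothing in the labels says whether replicates were separate donors or separate cultures, so the p-values measure only the spread between these samples. Total expected counts per library ran from 72498613 to 116044080. The spread between libraries of 1 group was 57.8 to 206 times what counting alone gives (chi-square per degree of freedom).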

Results

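Gene expression was measured by mRNA sequencing of sorted human dendritic cells grown from CD34+ progenitors. There were 3 libraries of cDC1 from culture on a DLL1 feeder, 3 from culture on an OP9 feeder, 3 from feeder-free culture, and 2 of cDC2 from culture on an OP9 feeder. Total expected counts were 72498613, 82446026 and 98804219 in the DLL1-feeder cDC1 and 97713577, 93653199 and 96526064 in the OP9-feeder cDC1. They were 73141892, 84211513 and 87729584 in the feeder-free cDC1 and 82067921 and 116044080 in the cDC2. Between 15402 and 17170 genes had at least 10 counts in a library. Mitochondrially encoded genes took 4.39%, 3.85% and 3.55% of counts in the DLL1-feeder cDC1, against 2.11% to 2.84% in the other cDC1 and 2.72% and 3.36% in the cDC2. The first principal component (53.9% of the variance) parted cDC2 from cDC1, and the second (15.2%) parted DLL1-feeder cDC1 from the other cDC1. Below, ± beside a log2 fold change is its standard error and ± beside a level is the SD, with n = 3 libraries in each cDC1 group and n = 2 for cDC2. A called gene named without a remark kept its call with each library of both groups left out in turn and under every other setting in which it was tested. This does not cover genes singled out after their values were seen, such as MALAT1, NEAT1, CCNL1 and NKTR. No leave-outs or alternatives were run for them.

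**Figure D1:**
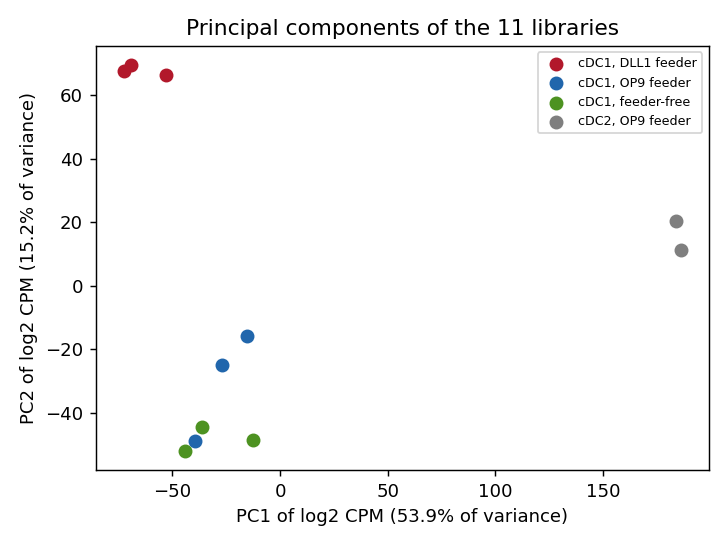
Each point is 1 of the 11 libraries, placed by its scores on the first principal component (horizontal, 53.9% of the variance) and the second (vertical, 15.2%) and coloured by group. The 2 cDC2 libraries lie at 184 and 186.1 on the first component, and the 3 DLL1-feeder cDC1 libraries at 66.4 to 69.4 on the second.

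The comparison of DLL1-feeder with OP9-feeder cDC1 asks what differs between cDC1 grown with the Notch ligand DLL1 and cDC1 grown on the other feeder. SLC38A11, an amino acid transporter family member (chromosome 2, 164896186 to 164955525, minus strand, GRCh38), was at 32.6 ± 11.1 CPM on the DLL1 feeder and had 1 count over the OP9-feeder libraries, a ratio of 8880 (95% counting interval 1590 to 351000, adjusted p = 0.000107). CDH17, a cadherin (chromosome 8, 94127171 to 94217303), was higher by a log2 fold change of 10.63 ± 1.06 (adjusted p = 0.000379) at 36.9 ± 37.3 against 0.0224 ± 0.0127 CPM. The small GTPase GEM (9.89 ± 1.16, adjusted p = 0.000843), the vesicular glutamate transporter SLC17A8 (5.86 ± 0.52, adjusted p = 0.000354) and the sodium leak channel NALCN (4.57 ± 0.94, adjusted p = 0.0118) were higher as well. IDO1 and IDO2, which break down tryptophan, rose by 3.6 ± 0.56 (adjusted p = 0.00281) and 3.99 ± 0.64 (adjusted p = 0.00319), IDO1 from 11.2 ± 4.86 to 136 ± 36.1 CPM. DNASE1L3, a secreted DNase, rose by 2.73 ± 0.49 (adjusted p = 0.00552). Among the lower genes were the water channel AQP1 (−8.28 ± 1.38, adjusted p = 0.00382; 0.307 ± 0.279 against 95.4 ± 126 CPM), the cytotoxic granule gene NKG7 (−4.85 ± 0.98, adjusted p = 0.0091) and ALOX5AP, a helper of 5-lipoxygenase (−3.93 ± 0.32, adjusted p = 0.000214).

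In all, 3514 of 18537 genes were called, 1964 higher and 1550 lower on the DLL1 feeder, of which 1049 and 292 changed at least 2-fold. This near balance did not hold on log2 TPM with a pseudocount of 1 (1621 higher, 292 lower) or 0.1 (1456 and 295), or in a fit of the 2 groups alone (1346 and 610). The cDC1 genes given whatever their result were not called: log2 fold changes were 0.03 for CLEC9A, 0.38 for XCR1, 0.04 for CADM1, −0.26 for THBD, −0.06 for BATF3, −0.33 for IRF8 (adjusted p = 0.0629), 0.57 for FLT3 (adjusted p = 0.0636) and −0.46 for TLR3. All cDC1 were sorted on CD141, the product of THBD, and on Clec9A. Similar THBD and CLEC9A levels among cDC1 groups, here or below, thus do not test whether culture changed cDC1 identity. DESeq2 called IRF8 (adjusted p = 0.00603) and FLT3 (0.025). FLT3 was also called without a low-count filter (0.0335), with the stricter filter (0.0432), on log2 TPM with a pseudocount of 1 (0.0492), among nuclear protein-coding genes alone (0.047) and without DLL1-feeder replicate 3 (0.0159). Of the cDC1 list, 5 of 29 members rose, IDO1 and IDO2 among them, with 6 higher and 3 lower when adjusted over the list alone, and the list was not called (adjusted p = 0.658). The cDC2 list fell, with 10 of 27 members lower (13 adjusted over the list alone) and a median log2 fold change of −0.65 (adjusted p = 5.5e-05, adjusted p = 0.114 with an estimated correlation). Within it, the adhesion receptor CD2 fell by 3.56 ± 0.36 on the log2 scale (adjusted p = 0.00039), the fractalkine receptor CX3CR1 was at −1.84 ± 0.27 (adjusted p = 0.00218) and the lipid-presenting CD1C at −1.15 ± 0.20 (adjusted p = 0.00416). CD1C went from 1001 ± 114 to 451 ± 108 CPM. FCER1A (−2.65 ± 0.98, adjusted p = 0.0858), CLEC10A (−0.63 ± 0.36, adjusted p = 0.244), IRF4 (−0.34 ± 0.51, adjusted p = 0.692) and CCR7 (0.31 ± 0.43, adjusted p = 0.668) were not called, but FCER1A was without a low-count filter (0.0115).

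Of 15 tested Notch target genes, 1 was higher and 1 lower on the DLL1 feeder than on OP9 (none adjusted over the list alone), and the list was not called (adjusted p = 0.402). HES4, a repressor induced by Notch, was at 9.33 ± 3.82 against 0.614 ± 0.738 CPM, a log2 fold change of 3.92 ± 1.04 (adjusted p = 0.0269). That call was lost without DLL1-feeder replicate 1 (adjusted p = 0.0567) or 2 (0.059) or without OP9-feeder replicate 2 (0.0873) or 3 (0.056). HES1 (2.57 ± 1.02, adjusted p = 0.106) and NRARP (−0.09 ± 0.25, adjusted p = 0.833) were not called. Of 27 receptor and machinery genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.658). Transcripts of the ligand gene DLL1 itself (chromosome 6, 170282206 to 170306565) were at 1.76 ± 0.164 CPM in the DLL1-feeder libraries, with 0 counts in the OP9-feeder cDC1, at least 162-fold higher (adjusted p = 0.000843), and 4 counts in the feeder-free cDC1 (6.63 ± 0.75, adjusted p = 0.000941). Whether these transcripts came from the cDC1 or from RNA of the feeder was not tested.

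Markers of other myeloid cells were lower on the DLL1 feeder than on OP9. Monocyte and macrophage markers fell in 9 of 29 members and rose in none (11 lower and 1 higher adjusted over the list alone), with a median of −1.19, or −1.12 with low-count members at their bound (adjusted p = 0.000419, adjusted p = 0.43 with an estimated correlation). The scavenger receptor MARCO fell by 3 ± 0.70 on the log2 scale (adjusted p = 0.0172). Granulocyte and mast cell markers fell in 3 of 21 members (9 adjusted over the list alone; median −1.68, or −1.48 at the bound, adjusted p = 0.0104, adjusted p = 0.652 with an estimated correlation), a call lost without DLL1-feeder replicate 1 (adjusted p = 0.0574). Stromal markers fell in 4 of 25 members (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.0403, adjusted p = 0.652 with an estimated correlation). This was lost without DLL1-feeder replicate 1 (0.148) or OP9-feeder replicate 3 (0.0868) and among nuclear protein-coding genes alone (0.0809). Fry called neither the granulocyte (0.15) nor the stromal list (0.085). The monocyte median was −0.35 or −0.77 and the granulocyte median −0.31 or −0.77 on log2 TPM with a pseudocount of 1 or 0.1. The collagens COL1A1 (−3.39 ± 0.46, adjusted p = 0.00148) and COL3A1 (−4.54 ± 0.83, adjusted p = 0.00596) and the matrix protein gene SPARC (−3.09 ± 0.56, adjusted p = 0.0056) were among them. The progenitor genes SPINK2 (−2.55 ± 0.48, adjusted p = 0.00687) and HOXA9 (−1.15 ± 0.14, adjusted p = 0.000879) and the lymphoid gene CD5 (−3.89 ± 0.78, adjusted p = 0.00907) were lower too.

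Nuclear genes of oxidative phosphorylation and mitochondrially encoded mRNAs moved in opposite directions on the DLL1 feeder against OP9, where the mitochondrial share of counts was also higher. The nuclear list fell, in 15 of 39 members (30 adjusted over the list alone; median −0.44, adjusted p = 5e-09, adjusted p = 0.647 with an estimated correlation). By contrast, 12 of 13 mitochondrial mRNAs rose (12 adjusted over the list alone; median 0.78, adjusted p = 4.72e-07, adjusted p = 0.427 with an estimated correlation), MT-ND6 by 1.83 ± 0.25 (adjusted p = 0.0016). In the same libraries the nuclear long noncoding RNAs MALAT1 (2.38 ± 0.25, adjusted p = 0.00048) and NEAT1 (2.87 ± 0.27, adjusted p = 0.000291), singled out after their values were seen, were higher. Cell cycle genes fell in 10 of 50 members (16 adjusted over the list alone; median −0.54, adjusted p = 4.72e-07, adjusted p = 0.652 with an estimated correlation). Genes of MHC class I presentation fell in 9 of 35 members and 1 rose (12 and 1 adjusted over the list alone; median −0.30, adjusted p = 0.000468, adjusted p = 0.169 with an estimated correlation), with the immunoproteasome subunit PSMB8 at −0.90 ± 0.14 (adjusted p = 0.00313). Interferon-stimulated genes fell in 6 of 44 members and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 0.0448, adjusted p = 0.652 with an estimated correlation). That list was lost without DLL1-feeder replicate 1 (0.148) or 2 (0.101) or OP9-feeder replicate 1 (0.0859) or 3 (0.148), and among nuclear protein-coding genes alone (0.12). That fit was added after seeing the data. Fry called neither the cell cycle nor the interferon list (adjusted p = 0.15 for each). Maturation genes were just short of a call as a list (7 of 32 higher, 1 lower, 8 and 1 adjusted over the list alone, adjusted p = 0.0501). Called members were CCL19, a chemokine of lymph node homing (4.99 ± 0.88, adjusted p = 0.00513), ICAM1 (1.54 ± 0.30, adjusted p = 0.00738) and TRAF1 (1.23 ± 0.12, adjusted p = 0.000379). Medians came to −0.23 for nuclear oxidative phosphorylation and −0.07 for MHC class I presentation on log2 TPM with either pseudocount. The sensors moved apart, with TLR8 higher by 2.04 ± 0.21 (adjusted p = 0.00039) and STING1 lower by −2.03 ± 0.23 (adjusted p = 0.000644).

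The 3514 calls rested in part on single libraries: without DLL1-feeder replicate 1 there were 1929, and without OP9-feeder replicate 2 there were 2165. A fit of the 2 groups alone called 1956.

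The comparison of DLL1-feeder with feeder-free cDC1 asks what a feeder presenting DLL1 changes against culture without any feeder. SLC38A11 was again among the higher genes, with no counts in the feeder-free libraries, at least 2580-fold (adjusted p = 6.11e-05). CDH17 (7.51 ± 0.86, adjusted p = 0.000464), GEM (6.76 ± 0.94, adjusted p = 0.00116), NALCN (4.88 ± 0.96, adjusted p = 0.00767) and the stress-induced glutathione-degrading enzyme gene CHAC1 (4.85 ± 0.84, adjusted p = 0.00362) were higher. Both GOLGA8A (4.96 ± 0.37) and GOLGA8B (4.60 ± 0.49) were called, but these near-identical copies share reads, so which of them changed is uncertain. The lower genes included CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 2, 38066973 to 38109902), at 0.0320 ± 0.0181 against 28.9 ± 8.64 CPM (−9.69 ± 0.77, adjusted p = 6.74e-05). The fatty acid binder FABP3 (−5.93 ± 0.41, adjusted p = 5.82e-05), ALOX5AP (−5.75 ± 0.34, adjusted p = 2.33e-05), the immunoglobulin joining chain JCHAIN (−6.72 ± 0.65, adjusted p = 0.000194) and the carboxylesterase CES1 (−5.08 ± 0.72, adjusted p = 0.00128) were lower.

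Of 18537 genes, 4445 were called, 2483 higher and 1962 lower on the DLL1 feeder, with 1465 and 304 changed at least 2-fold. On log2 TPM with a pseudocount of 1 there were 1815 higher and 576 lower. The cDC1 markers CLEC9A (0.12), XCR1 (0.05), CADM1 (−0.03), THBD (−0.13), BATF3 (0.29), IRF8 (−0.18) and TLR3 (−0.36) were not called. FLT3, the receptor for a growth factor of dendritic cells, was at 0.55 ± 0.19 and was not called (adjusted p = 0.0607). It was called with the replicate block (0.0351, or 0.0128 in the blocked fit of these 2 groups alone), by DESeq2 (0.0281), without a low-count filter (0.0311), with the stricter filter (0.0412), among nuclear protein-coding genes alone (0.0439) and without DLL1-feeder replicate 3 (0.0142). In the cDC1 list 5 of 29 members rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.353, though fry called it higher at 0.0221). Among them were IDO1 (2.96 ± 0.54, adjusted p = 0.00468), IDO2 (3.24 ± 0.62, adjusted p = 0.00544) and the inhibitory receptor BTLA (4.51 ± 0.53, adjusted p = 0.000511). The cDC2 list fell in 6 of 27 members and rose in 1 (7 and 1 adjusted over the list alone; median −0.42, adjusted p = 0.0361, adjusted p = 0.631 with an estimated correlation). The call was lost without DLL1-feeder replicate 2 (0.0821) or feeder-free replicate 2 (0.0686) and among nuclear protein-coding genes alone (0.12), and the median was −0.22 on log2 TPM with a pseudocount of 1. CD2 (−2.19 ± 0.35, adjusted p = 0.00234) and SIRPA (−1.45 ± 0.26, adjusted p = 0.00441) were lower. CLEC10A was lower too (−1.42 ± 0.36, adjusted p = 0.019), a call lost without feeder-free replicate 1 (0.0631). CD1C (−0.42 ± 0.19, adjusted p = 0.143), FCER1A (−1.34 ± 0.95, adjusted p = 0.336) and IRF4 (0.24 ± 0.52, adjusted p = 0.788) were not called.

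Notch target genes were not called as a list against feeder-free culture (3 of 15 higher and 2 lower, 3 and 2 adjusted over the list alone, adjusted p = 0.738). HES4 was at 9.33 ± 3.82 against 0.606 ± 0.743 CPM (3.94 ± 1.04, adjusted p = 0.0217), which was lost without feeder-free replicate 1 (0.0711) or 3 (0.0625). HES1, another such repressor, had 3 counts in the feeder-free libraries and a ratio of 19.5 (95% counting interval 6.68 to 94.6, adjusted p = 0.0338). Its call was lost with the replicate block over all libraries (0.0539), and HES1 was not tested in the blocked fit of these 2 groups alone. The call was also lost without DLL1-feeder replicate 2 (0.104) or 3 (0.0526), and without feeder-free replicate 1 (0.0575), 2 (0.0979) or 3 (0.0993). NRARP was at 0.48 ± 0.25 (adjusted p = 0.185). Among receptors and machinery, 4 of 27 rose and 2 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.801). NOTCH4 (1.83 ± 0.38, adjusted p = 0.00789) and the ligand JAG2 (1.59 ± 0.33, adjusted p = 0.00835) were higher.

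Maturation and migration genes rose as a list on the DLL1 feeder against feeder-free culture, in 10 of 32 members (10 adjusted over the list alone; median 0.49, adjusted p = 0.0126, adjusted p = 0.631 with an estimated correlation), which was lost without DLL1-feeder replicate 3 (0.0568). CCR7, which guides dendritic cells to lymph nodes, rose from 1.18 ± 0.754 to 5.89 ± 1.93 CPM (2.32 ± 0.46, adjusted p = 0.00666). Its ligand gene CCL19 had 1 count in the feeder-free libraries, a ratio of 179 (95% counting interval 32.2 to 7080, adjusted p = 0.00196). The cytokine TNF rose from 62.7 ± 14.7 to 286 ± 84.7 CPM (2.19 ± 0.29, adjusted p = 0.000874). The growth factor VEGFA rose by 2.79 ± 0.26 (adjusted p = 0.000171) and TLR10, a Toll-like receptor gene, by 2.97 ± 0.24 (adjusted p = 6.97e-05). Cytokines as a list were not called (5 of 33 higher, 2 lower, 5 and 2 adjusted over the list alone, adjusted p = 0.84). Immediate-early and heat-shock genes were mixed, 16 of 32 higher and 8 lower (18 and 8 adjusted over the list alone; median 0.79, adjusted p = 0.0425, adjusted p = 0.631 with an estimated correlation). FOSB was at 3.30 ± 0.34 (adjusted p = 0.000288) and NR4A2 at 2.03 ± 0.30 (adjusted p = 0.00148). The list's call was lost without DLL1-feeder replicate 2 (0.0849) or 3 (0.0753) or feeder-free replicate 3 (0.0891). NFKBIZ, a regulator of NF-kB, rose by 3.37 ± 0.31 (adjusted p = 0.000175), and the class II transactivator CIITA by 1.05 ± 0.15 (adjusted p = 0.00132).

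As against OP9, nuclear oxidative phosphorylation genes and mitochondrially encoded mRNAs parted against feeder-free culture, beside the higher mitochondrial share of the DLL1-feeder libraries. The nuclear list fell in 26 of 39 members (30 adjusted over the list alone; median −0.42, adjusted p = 4.6e-10), with NDUFA4 at −0.75 ± 0.13 (adjusted p = 0.00302). Mitochondrial mRNAs rose in 9 of 13 (10 adjusted over the list alone; median 0.56, adjusted p = 0.000393), with MT-ND6 at 2.08 ± 0.25 (adjusted p = 6e-04). MALAT1 (2.73 ± 0.26, adjusted p = 0.000183) and NEAT1 (3.67 ± 0.28, adjusted p = 6.11e-05), singled out as above, were again higher, as were CCNL1 (2.58 ± 0.21, adjusted p = 6.79e-05) and NKTR (2.32 ± 0.26, adjusted p = 0.000447), also singled out after their values were seen. Cell cycle genes fell in 21 of 50 members (29 adjusted over the list alone; median −0.65, adjusted p = 6.32e-09), with CDK1 at −0.95 ± 0.23 (adjusted p = 0.0144). Cholesterol and fatty acid synthesis genes fell in 6 of 30 and rose in 1 (9 and 1 adjusted over the list alone; median −0.35, adjusted p = 0.000393), with INSIG1, a brake on sterol synthesis, at −0.87 ± 0.16 (adjusted p = 0.0045). For each of these 4 lists the result was adjusted p = 0.631 with an estimated correlation. Fry called neither the cell cycle list (0.0848) nor cholesterol and fatty acid synthesis (0.0927). MHC class I presentation fell in 9 of 35 members and rose in 2 (10 and 2 adjusted over the list alone; median −0.25, adjusted p = 0.0126, adjusted p = 0.631 with an estimated correlation). That call was lost without DLL1-feeder replicate 2 (0.0634) and among nuclear protein-coding genes alone (0.0675). Monocyte and macrophage markers fell in 6 of 29 (5 adjusted over the list alone, adjusted p = 0.0225, adjusted p = 0.631 with an estimated correlation). They were not called with the replicate block over all libraries (0.0529) but were in the blocked fit of these 2 groups alone (0.0118). The call was lost without DLL1-feeder replicate 2 (0.0634) or feeder-free replicate 2 (0.252), among nuclear protein-coding genes alone (0.0675) and by fry (0.0927). Medians of cholesterol and fatty acid synthesis and of MHC class I presentation came to −0.23 and −0.11 on log2 TPM with either pseudocount. Stromal markers were not called as a list, with 6 of 25 higher (6 adjusted over the list alone, adjusted p = 0.162). FN1 was at 3.39 ± 0.49 (adjusted p = 0.00145) and COL1A2 at 4.24 ± 0.80 (adjusted p = 0.00513). Leaving out feeder-free replicate 1, 2 or 3 brought the calls from 4445 to 2764, 2763 or 2888, and leaving out DLL1-feeder replicate 2 brought the called lists from 9 to 5.

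The comparisons of DLL1-feeder cDC1 with OP9-feeder and with feeder-free cDC1 shared many calls. Higher in both were 1573 genes, where independence gives 263.1, and lower in both were 1069, where it gives 164.1. Both comparisons use the same DLL1-feeder libraries. In 20 simulations of unchanged groups sharing libraries in this way, 0 genes were higher and 0 lower in both. As no simulation called more than 1 gene higher against OP9 and none against feeder-free culture, they do not tell how much of the excess comes from the shared libraries. Opposite calls were made for 5 genes, EPB41L3, RNF24, COL1A1, SPARC and PIK3R3, named after their values were seen. Long noncoding genes were seldom called lower: 311 of 2589 tested were higher and 35 lower on the DLL1 feeder against OP9, and 433 and 38 against feeder-free culture. Pseudogenes did the same, with 140 of 1888 higher and 15 lower, and 188 and 18. Protein-coding genes split 1487 to 1497 and 1822 to 1901 of 13755. Over all genes, calls of at least 2-fold were 1049 higher and 292 lower against OP9, and 1465 and 304 against feeder-free culture. Higher calls outside the coding class are too few to make that excess, so it extends to large changes of protein-coding genes. Classes were not compared at matched level or size of change. Against feeder-free culture, fits without DLL1-feeder replicate 1 or feeder-free replicate 1, 2 or 3 called 281, 285, 256 or 274 long noncoding genes higher. Against OP9, fits without DLL1-feeder replicate 1 or OP9-feeder replicate 2 or 3 called 166, 190 or 188. Against each other, OP9-feeder and feeder-free cDC1 had 3 long noncoding genes higher and 4 lower.

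**Figure D2:**
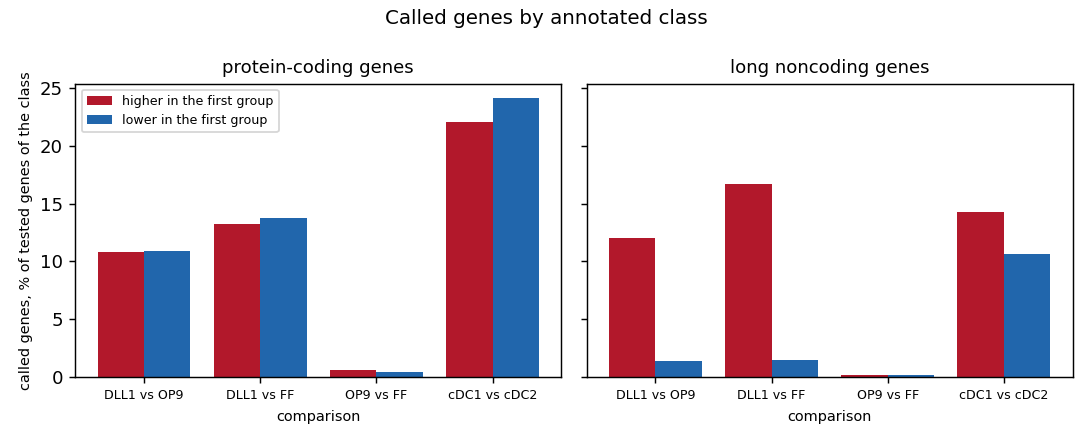
Bars give the called genes, higher and lower, as a percentage of tested genes of each class (vertical axis) for the 4 comparisons (horizontal axis). Long noncoding genes were higher on the DLL1 feeder in 12% (against OP9) and 16.7% (against feeder-free) of those tested and lower in 1.35% and 1.47%.

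**Figure D3:**
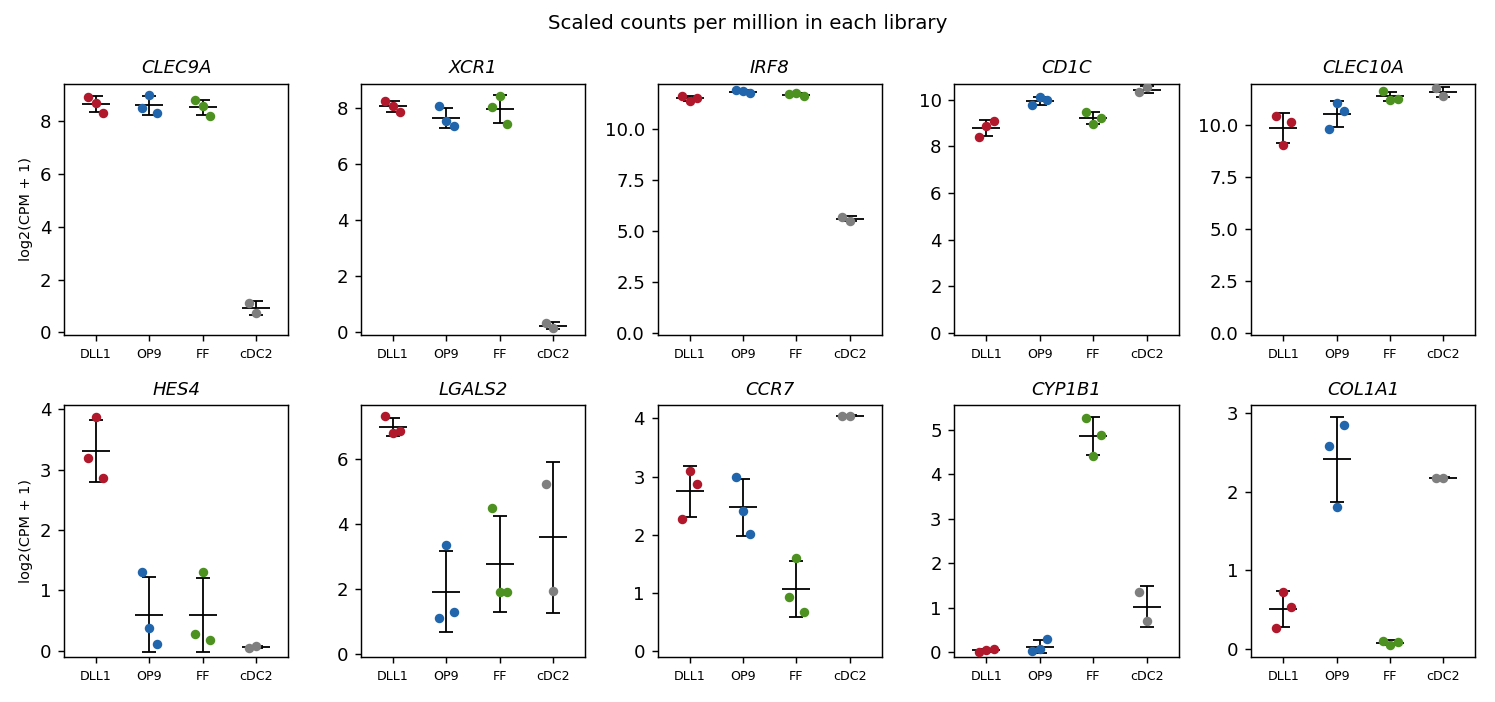
Each panel shows 1 gene as log2(CPM + 1) per library (points) with the group mean and SD (line and bar) for DLL1-feeder, OP9-feeder and feeder-free cDC1 and for cDC2. CLEC9A, a marker the cDC1 were sorted on, lies at mean levels of 407, 399 and 373 CPM in the 3 cDC1 groups and at 0.899 CPM in cDC2. HES4 lies at 9.33, 0.614 and 0.606 CPM in the cDC1 groups.

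The comparison of OP9-feeder with feeder-free cDC1 gives the background of a feeder other than the DLL1 feeder. COL1A1, a collagen made by stromal cells (chromosome 17, 50183289 to 50201632), was at 4.58 ± 1.89 against 0.0590 ± 0.0199 CPM (6.25 ± 0.55, adjusted p = 0.00178), a call lost on log2 TPM with a pseudocount of 1 (adjusted p = 0.0728). The phosphatase gene DUSP6, a target of ERK signalling, was higher by 2.63 ± 0.20 (adjusted p = 0.000919), BTLA by 5 ± 0.53 (adjusted p = 0.0043). Also higher were the scaffold gene DLG3 by 2.87 ± 0.36 (adjusted p = 0.00829) and the chemokine receptor CCR2 by 1.28 ± 0.15 (adjusted p = 0.00613). Of the aryl hydrocarbon receptor targets, 3 of 10 fell (3 adjusted over the list alone, adjusted p = 9.79e-05, adjusted p = 0.146 with an estimated correlation): CYP1B1 (−8.18 ± 0.69, adjusted p = 0.00145), TIPARP (−1.90 ± 0.19, adjusted p = 0.00385) and the receptor's repressor AHRR (−1.71 ± 0.21, adjusted p = 0.00829). FABP3 was lower by −3.04 ± 0.35 (adjusted p = 0.00625). None of the cDC1 markers CLEC9A (0.10), XCR1 (−0.33), CADM1 (−0.08), THBD (0.13), BATF3 (0.35), IRF8 (0.14), FLT3 (−0.02) and TLR3 (0.10) was called. Nor were HES4 (0.02), NRARP (0.57), IRF4 (0.57), FCER1A (1.31), CLEC10A (−0.79), CD1C (0.73 ± 0.19, adjusted p = 0.15) or CCR7 (2.02 ± 0.46, adjusted p = 0.0964), of which CD1C and CCR7 were called by DESeq2 (0.0139 and 0.000346) and without a low-count filter (0.0356 and 0.00244). CCR7 was also called without feeder-free replicate 2 (0.0458). HES1 had 3 counts in the feeder-free libraries, a ratio of 3.20 (95% counting interval 1.09 to 15.5, adjusted p = 0.793).

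In all, 139 genes were called between OP9-feeder and feeder-free cDC1, 81 higher and 58 lower, with 1974 at an unadjusted p under 0.05. By limma on log2 TPM more genes were lower than higher, with 29 higher and 39 lower at a pseudocount of 1 and 34 and 38 at 0.1. DESeq2 called 622, and leaving out single libraries gave 42, 56 and 35 without feeder-free replicate 1, 2 and 3, and 37 and 47 without OP9-feeder replicate 1 and 3. Immediate-early and heat-shock genes rose in 7 of 32 members (18 higher and 1 lower adjusted over the list alone; median 0.78, adjusted p = 9.36e-08). Stromal markers rose in 5 of 25 (8 adjusted over the list alone; median 1.00, or 0.67 with low-count members at their bound, adjusted p = 3.57e-07), and cDC2 markers in 2 of 27 (6 higher and 1 lower adjusted over the list alone; median 0.39, adjusted p = 0.00326). For each of these lists the result was adjusted p = 0.146 with an estimated correlation. Granulocyte and mast cell markers rose as a list with 1 of 21 called (1 adjusted over the list alone; median 1.59, or 1.00 at the bound, adjusted p = 0.000506). Cholesterol and fatty acid synthesis fell with 1 of 30 called (3 adjusted over the list alone; median −0.27, adjusted p = 2.39e-07). Both lists were at adjusted p = 0.622 with an estimated correlation. On log2 TPM with a pseudocount of 1 the medians came to 0.49 for immediate-early genes, 0.48 for stromal and 0.21 for granulocyte markers. Mitochondrially encoded mRNAs were lower as a list with none of 13 called (none adjusted over the list alone; median −0.22, adjusted p = 0.00326, adjusted p = 0.713 with an estimated correlation). Cytokines were higher as a list with none of 33 called (5 adjusted over the list alone, adjusted p = 0.00267, adjusted p = 0.609 with an estimated correlation), lost without feeder-free replicate 3 (0.0604). Cell cycle genes, with none of 50 called (none adjusted over the list alone), were lower as a list (adjusted p = 0.0353, adjusted p = 0.86 with an estimated correlation). This was lost without feeder-free replicate 2 (0.0727) or 3 (0.0984) or OP9-feeder replicate 2 (0.145) or 3 (0.432) and among nuclear protein-coding genes alone (0.0975). Notch targets (0 of 15, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.477; median 0.01, which changed sign on TPM) and machinery genes (0 of 27, none adjusted over the list alone, adjusted p = 0.772) were not called.

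The comparison of OP9-feeder cDC1 with OP9-feeder cDC2 shows what parts the 2 cell types under the same culture. The sort markers CD141, Clec9A, CD1c and FCERA defined these groups, so differences in CLEC9A, THBD and CD1C were partly set by the sort. The dead-cell receptor CLEC9A (chromosome 12, 10030677 to 10066027) was at 399 ± 103 CPM in cDC1 and 0.899 ± 0.345 in cDC2 (8.82 ± 0.42, adjusted p = 3.04e-07). XCR1, a chemokine receptor (10.21 ± 0.53, adjusted p = 3.99e-07), CADM1, an adhesion molecule (10 ± 0.35, adjusted p = 6.04e-08), and IRF8, the transcription factor of the cDC1 lineage (6.24 ± 0.17, adjusted p = 1.48e-08), were higher in cDC1. So were THBD (3.54 ± 0.28), TLR3 (3.45 ± 0.24), FLT3 (2.66 ± 0.24) and BATF3 (1.38 ± 0.16). IRF4, a factor of the cDC2 lineage, was lower by −5.32 ± 0.60 (adjusted p = 5.84e-05). Also lower were the macrophage growth factor receptor CSF1R (−7.40 ± 0.68, adjusted p = 1.48e-05), the integrin ITGAM (−7.44 ± 0.79, adjusted p = 4.14e-05), the transcription factor ZEB2 (−6.56 ± 0.70, adjusted p = 4.09e-05) and the lectin FCN1 (−8.38 ± 0.88, adjusted p = 3.58e-05). Among genes without counts in cDC2, PPY was at least 392-fold and RHOD at least 378-fold higher in cDC1, and CTNND2 with 3 counts had a ratio of 2970 (95% counting interval 1020 to 14400). CD1C (−0.47 ± 0.21, adjusted p = 0.108), FCER1A (−2.82 ± 1.04, adjusted p = 0.0535) and CLEC10A (−1 ± 0.39, adjusted p = 0.0663) were not called here, and were called by limma on log2 TPM with a pseudocount of 1 (0.0288, 0.0434 and 0.0137) and of 0.1 (0.0286, 0.0476 and 0.0136). DESeq2 called CD1C (0.0486) and CLEC10A (0.0167), and without a low-count filter FCER1A (0.00419) and CLEC10A (0.0162) were called. FCER1A was also called with RLE size factors (0.0492), a stricter low-count filter (0.0453), only the 2 groups (0.0205) and nuclear protein-coding genes alone (0.043). It was called without OP9-feeder cDC1 replicate 1 (0.0432) and CLEC10A without replicate 2 (0.0346). CCR7 was lower in cDC1 (−1.70 ± 0.48, adjusted p = 0.0163), a call lost without cDC2 replicate 1 (0.0554) or 2 (0.0631).

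Between cDC1 and cDC2, 7315 genes were called, 3596 higher and 3719 lower in cDC1. By limma on log2 TPM the split was 1828 higher to 3334 lower with a pseudocount of 1 and 1939 to 3269 with 0.1. The cDC1 list rose in 28 of 29 members (29 adjusted over the list alone; median 3.45, adjusted p = 9e-20, adjusted p = 0.00335 with an estimated correlation). The cDC2 list fell in 17 of 27 and rose in 2 (19 and 2 adjusted over the list alone; median −2.65, adjusted p = 1.03e-06, adjusted p = 0.0236 with an estimated correlation). These are the 2 lists that hold with an estimated correlation. Cell cycle genes were higher in 45 of 50 and lower in 1 (47 and 1 adjusted over the list alone; median 1.16, adjusted p = 4.99e-10, adjusted p = 0.379 with an estimated correlation), PLK1 by 1.85 ± 0.26 (adjusted p = 0.000291). Glycolysis and hypoxia genes fell in 22 of 31 and rose in 1 (25 and 1 adjusted over the list alone; median −0.91, adjusted p = 1.03e-06, adjusted p = 0.222 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 22 of 30 (24 adjusted over the list alone; median −0.79, adjusted p = 9.65e-07, adjusted p = 0.354 with an estimated correlation). Maturation genes were lower in 19 of 32 and higher in 1 (20 and 1 adjusted over the list alone; median −1.65, adjusted p = 1.22e-05, adjusted p = 0.253 with an estimated correlation). Among them were CCL17 (−5.12 ± 0.57, adjusted p = 5.81e-05), CD274 (−4.47 ± 0.70, adjusted p = 0.00056) and PDCD1LG2 (−4.78 ± 0.61, adjusted p = 0.000135). MHC class I presentation was higher in 18 of 35 and lower in 5 (18 and 5 adjusted over the list alone; median 0.51, adjusted p = 0.0195, adjusted p = 0.222 with an estimated correlation). NLRC5, its transactivator, was higher by 4.25 ± 0.30 (adjusted p = 3e-06). Notch targets were higher in 6 of 15 and lower in 5 (8 and 5 adjusted over the list alone, list adjusted p = 0.417). Fry, by contrast, called this list higher in cDC1 (adjusted p = 0.000145). NRARP was at 1.63 ± 0.29 (adjusted p = 0.00137), HES4 at 3.74 ± 1.44 (adjusted p = 0.0618) and HES1 at −1.70 ± 1.11 (adjusted p = 0.261). HES4 was called by DESeq2 (0.0132), without a low-count filter (0.00874) and without OP9-feeder cDC1 replicate 3 (0.0285). On log2 TPM the MHC class I median was 0.30 with either pseudocount.

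Markers of other myeloid cells were more abundant in the cDC2 than in the cDC1 libraries. Monocyte and macrophage markers were lower in cDC1 in 21 of 29 members and higher in 2 (22 and 2 adjusted over the list alone; median −2.98, adjusted p = 1.22e-05, adjusted p = 0.222 with an estimated correlation), with MRC1 at −8.08 ± 0.98 (adjusted p = 0.000102). Granulocyte and mast cell markers were lower in 14 of 21 and higher in 1 (14 and 3 adjusted over the list alone; median −5.42, adjusted p = 0.000207, adjusted p = 0.332 with an estimated correlation), with RNASE2 at −9.08 ± 1.11 (adjusted p = 0.000105). The granulocyte median was −2.80 on log2 TPM with a pseudocount of 1. PRG2, the eosinophil granule major basic protein, was at 122 ± 170 CPM in cDC2 against 0.174 ± 0.284 in cDC1, and its call was lost without cDC2 replicate 2 (adjusted p = 0.251). The progenitor marker CD34 was lower in cDC1 by −6.63 ± 0.84 (adjusted p = 0.000132). With only 2 cDC2 libraries, a fit without 1 of them assumes that the other varies like the remaining groups.

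**Figure D4:**
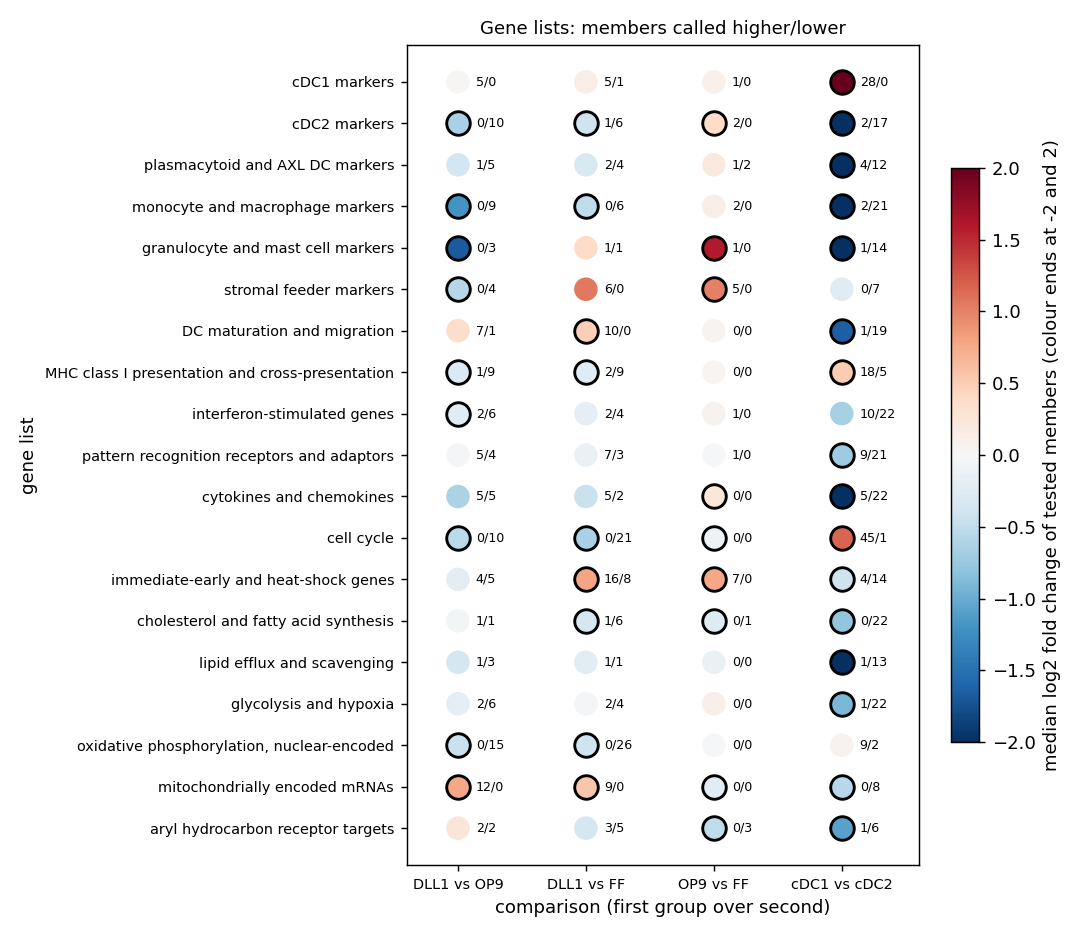
Each dot is 1 gene list (vertical axis) in 1 comparison (horizontal axis, first group over second), coloured by the median log2 fold change of its tested members, with a black ring where the camera adjusted p was under 0.05 and the numbers of members called higher and lower written beside it. Rings mark 9 lists in each comparison among cDC1 and 16 between cDC1 and cDC2.

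Genes that part cDC1 from cDC2 were tested as sets between DLL1-feeder and feeder-free cDC1, a comparison that shares no library with the one they were chosen on. Of the 200 genes most above cDC2 in cDC1, 48 were higher and 15 lower on the DLL1 feeder (median 0.44, adjusted p = 0.00819), and of the 200 most above cDC1 in cDC2, 6 were higher and 22 lower (median −0.965, adjusted p = 0.0027). Over all 18537 genes, 2483 were called higher and 1962 lower, so the share called lower in the second set was near that of all genes. Medians with low-count members at their bound or on TPM were not computed for these sets. Each set gave adjusted p = 0.346 with an estimated correlation. Without feeder-free replicate 2 both calls were lost (0.0537 and 0.0975), and with the top 100 genes the first was lost (0.0613) and the second kept (0.0136).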

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

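The tests for RNA of feeder cells, for stray reads and for left-over cDC2 and the long noncoding counts without single OP9-feeder or feeder-free libraries were chosen only after the results they bear on had been seen, as were the 3 patterns weighed. Each of the 9 genes named next was called in all 3 comparisons among cDC1. The difference of its 2 effects against feeder-free culture is the contrast of DLL1-feeder with OP9-feeder cDC1, 1 of the 3 the genes were chosen on, so its p-value is no further test. Both effects share the feeder-free libraries. ALOX5AP was at −1.81 on OP9 and −5.75 on the DLL1 feeder, a difference of −3.93 ± 0.32 (adjusted p = 0.000214). FABP3 was at −3.04 and −5.93, a difference of −2.89 ± 0.38 (adjusted p = 0.0014), and JCHAIN at −2.99 and −6.72, a difference of −3.73 ± 0.66 (adjusted p = 0.00512). CCR2 was at 1.28 and −0.51 (−1.79 ± 0.15, adjusted p = 0.000214), and MCC at −1.74 and 0.89 (2.63 ± 0.19, adjusted p = 0.000107). COL1A1 was at 6.25 and 2.86 (−3.39 ± 0.46, adjusted p = 0.00148), and SPARC at 5.37 and 2.29 (−3.09 ± 0.56, adjusted p = 0.0056). TLR10 was at 1.57 and 2.97 (1.40 ± 0.23, adjusted p = 0.00319). FOSB was at 2.28 and 3.30 (1.02 ± 0.31, adjusted p = 0.0464), a difference lost without DLL1-feeder replicate 1 (0.0955), 2 (0.113) or 3 (0.0656) or OP9-feeder replicate 2 (0.119) or 3 (0.117) and in a fit of the 2 groups alone (0.0669). Some effects of OP9 lost their call without feeder-free replicate 1, 2 or 3 or OP9-feeder replicate 1 or 3. These were ALOX5AP (0.0831 without feeder-free 1, 0.0586 without 3, 0.0751 without OP9 1, 0.0525 without 3), TLR10 (0.0831, 0.0588 and 0.0669 without feeder-free 1, 2 and 3, 0.0589 without OP9 1), SPARC (0.0531 without feeder-free 3) and FOSB (0.0629 and 0.0586 without feeder-free 2 and 3, and 0.0631 in a fit of the 2 groups alone). JCHAIN lost it without any 1 of the 6 libraries (0.0557 to 0.0828). On log2 TPM with a pseudocount of 1, calls were lost for COL1A1 on the DLL1 feeder (0.761, and 0.448 with a pseudocount of 0.1) and on OP9 (0.0728), for MCC on OP9 (0.0501) and for the difference of JCHAIN (0.118).

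Long noncoding genes were called higher far more often than lower on the DLL1 feeder, as were pseudogenes, whose calls the tests here do not cover. Calls of at least 2-fold leaned the same way over all genes (1465 higher and 304 lower against feeder-free culture), so the lean was not particular to noncoding genes. Trends with GC content and the length of the longest transcript were removed in a limma fit on log2 CPM, blocked by replicate number. Against feeder-free culture this changed 3090 calls. It left 467 long noncoding genes higher and 98 lower, from 495 and 55, and their median went from 0.36 to 0.22. Protein-coding genes went from 2007 higher and 2140 lower to 1556 and 4418, and their median from −0.04 to −0.21. The removal also took out each library's mean deviation over genes, so both medians fell together. The counts and medians therefore do not tell whether such trends are a part of the cause. That long noncoding genes stayed mostly higher argues against such trends as the whole cause. Fits without DLL1-feeder replicate 1, 2 or 3 called 281, 352 or 348 long noncoding genes higher and 27, 42 or 32 lower, against 433 and 38, and fits without feeder-free replicate 1, 2 or 3 called 285, 256 or 274 higher and 19, 25 or 22 lower, so no 1 of these 6 libraries made the excess of higher over lower. A candidate explanation is a larger share of nuclear RNA in the DLL1-feeder libraries: 4 nuclear long noncoding RNAs chosen by name lay 0.75 above 8 cytoplasmic ones (medians 0.95 and 0.2, exact permutation p = 0.0242, two-sided; against OP9 0.45, p = 0.097). As first run with KCNQ1OT1, taken out after that result because its value had been seen, the difference was 1.05 (exact permutation p = 0.00777, against OP9 0.45, p = 0.0746). Single members were mixed: nuclear PVT1 (1.95) and LINC-PINT (1.31) lay above every cytoplasmic one. Cytoplasmic CYTOR (0.82) lay above nuclear TUG1 (0.37) and HOTAIRM1 (0.59). SNHG12, on neither list but named like the cytoplasmic SNHG5 (0.13), rose by 3.23 ± 0.3 and was singled out after its value was seen. An effect of the ligand stays open and untested, as does whether a change in RNA composition also lowered the lists that fell in these libraries.

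Stromal transcripts were present in the OP9-feeder libraries of both cell types, with COL1A1 at 4.58 CPM in cDC1 and 3.53 CPM in cDC2 against 0.434 on the DLL1 feeder and 0.059 in feeder-free culture, and FN1 at 1.8, 2.15, 0.758 and 0.0716 CPM. The SD of the log2 ratio of COL1A1 to COL1A2 over the 5 OP9-feeder libraries was 0.17 around a mean of 1.63. Any 1 source of both transcripts, feeder cells or not, would give such a steady ratio, so it does not tell the source. RNA of feeder cells may have entered the libraries. In DLL1-feeder cDC1 the 2 collagens were at 0.434 ± 0.225 and 0.411 ± 0.331 CPM. SPARC, at 1.08 ± 0.361 CPM in OP9-feeder cDC1 and 5.57 ± 1.87 CPM in cDC2, did not keep 1 ratio to COL1A1, which 1 source alone does not explain. Whether the sort on CD141 and Clec9A, or on CD1c and FCERA, removed all such cells and their RNA was not tested. OP9 is a mouse line while the build was hg38, so how much of its RNA these counts would hold is unknown. Whether a few genes with stray reads make the pattern cannot be told apart: 9 of 25 members (36%) had every OP9-feeder cDC1 library above every feeder-free one, against 9.34% of all tested genes and 5% by chance, and the counts are low. Expression by the dendritic cells themselves was not tested. The DLL1-feeder libraries held DLL1 transcripts at 1.76 ± 0.164 CPM, which may be RNA of that feeder, and this source was not tested either.

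The cDC2 markers were lower as a list in DLL1-feeder than in OP9-feeder cDC1 with 10 of 27 called lower, though not with an estimated correlation (adjusted p = 0.114). Left-over cDC2 in the OP9-feeder sort would need the same share of cDC2 RNA for each of the 10 called members, but the shares ran from 0.409% to 64.3%, which argues against it for the list as a whole but leaves it open for CD1E, CSF1R, ITGAM and SIRPA, at 0.409%, 0.453%, 0.515% and 0.634%. For 21 abundant genes restricted to cDC2, the shares had quartiles of 0.31% and 0.503%, first read as a match; the member test and a choice of 45 genes on cDC2 over feeder-free cDC1 (0.396% to 1.22%) were then added, and the reading became open, because choosing genes on their OP9-feeder level caps the share. Removing trends with GC content and length left the list's median at −0.72, from −0.65 (camera adjusted p = 0.00138), which argues against such trends. The removal shifted other genes too, with the protein-coding median going from −0.05 to −0.16, but camera compares the list with them. An effect of the ligand on these genes stays open as a hypothesis.

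In the splits of the 6 libraries into 3 and 3, 10 splits are too few for a share under 0.05. The real split gave 3514 called genes for DLL1-feeder against OP9-feeder cDC1 and the highest other 0, with 1 of 10 splits as large. It gave 4445 against feeder-free culture and the highest other 1, and 139 for OP9-feeder against feeder-free cDC1 and the highest other 3, again 1 of 10 in each.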

How the results depend on the processing

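The fits of nuclear protein-coding genes alone and of the DLL1-feeder and feeder-free libraries alone with a block were chosen only after the results were seen. No called result described reversed its direction under any alternative, though medians of uncalled lists changed sign on TPM, and the cause of each change given here was not tested unless stated. Named genes that kept their call under every alternative and leave-out numbered 49 of 119 for DLL1-feeder against OP9-feeder cDC1, 68 of 111 for DLL1-feeder against feeder-free, 9 of 37 for OP9-feeder against feeder-free and 108 of 126 for cDC1 against cDC2, and lists 0 of 9, 0 of 9, 0 of 9 and 2 of 16. OP9-feeder against feeder-free cDC1 had 622 called genes with DESeq2, 331 without a low-count filter, and 68 and 72 on log2 TPM with a pseudocount of 1 and 0.1. On these scales DLL1-feeder against OP9-feeder cDC1 had 1913 and 1751, of which 84.7% and 83.2% were higher against 55.9%, and DLL1-feeder against feeder-free 2391 and 2298. The median over the 13736 genes of the TPM fits, which differ in scale, method and filter, lay 0.103 and 0.126 from that over the 18537 genes for DLL1-feeder against OP9-feeder cDC1 and −0.163 and −0.193 from it for cDC1 against cDC2. A fit of only the 2 groups gave 1956 for DLL1-feeder against OP9-feeder cDC1. With an estimated correlation 0, 0, 0 and 2 lists were called in the 4 comparisons, and fry called 4 for OP9-feeder against feeder-free and 24 for cDC1 against cDC2. Of the 9 lists camera called in each DLL1-feeder comparison, fry kept 5 against OP9 and 6 against feeder-free culture. It also called plasmacytoid, lymphoid and progenitor markers lower in both, which camera did not. Against feeder-free culture it further called cDC1 markers higher and aryl hydrocarbon receptor targets lower. Nuclear protein-coding genes alone left 5 lists for DLL1-feeder against feeder-free cDC1. The cDC1 set of the signature was at 0.0613 with the top 100 genes, and both sets at 0.346 and 0.346 with an estimated correlation. With 1 library left out in turn, called genes ran from 1929 (without DLL1-feeder replicate 1) to 3026, from 2763 (without feeder-free replicate 2) to 4093, from 35 (without feeder-free replicate 3) to 107 and from 5199 to 6795. Lists ran from 7 to 12, from 5 (without DLL1-feeder replicate 2) to 11, from 8 to 10 and from 15 to 20. Signature p-values ran from 0.00102 to 0.0537 for the cDC1 set and from 2.3e-05 to 0.0975 for the cDC2 set, both highest without feeder-free replicate 2. The replicate block gave 3588, 4589, 152 and 7196 genes and 8, 8, 9 and 19 lists. Between DLL1-feeder and feeder-free cDC1, which the numbers pair, it changed the calls of HES1, FLT3 and the monocyte list and no other call described. The blocked fit of these 2 groups alone called 5584 genes (3096 higher, 2488 lower, 4082 of them shared with the 4445) and kept 9 of 9 lists. Among the other groups, same-number correlations ran down to −0.35. OP9-feeder replicate 1 correlated best with number 2 of every other group (0.48 with DLL1-feeder, 0.44 with feeder-free) and replicate 2 with number 1 (0.32 and 0.41). Replicate 3 correlated best with its own number (0.33 and 0.41). These values are similar to those taken to pair DLL1-feeder with feeder-free libraries. The OP9 libraries may thus be paired under exchanged numbers. No fit made this pairing, so the comparisons with OP9-feeder cDC1 leave it out, and the block by number does not test it. The block over all libraries rests on these numbers too. Its values for DLL1-feeder against feeder-free cDC1 are therefore not a clean paired test. Simulations with these depths missed part of the 2-fold changes, so an uncalled gene is not shown to be unchanged.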

Other observations

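Further gene lists parted cDC1 from cDC2 on OP9. Lipid efflux and scavenging genes were lower in cDC1 in 13 of 20 members and higher in 1 (15 and 2 adjusted over the list alone, median −2.25, adjusted p = 0.000207, adjusted p = 0.222 with an estimated correlation), with PPARG at −5.22 ± 0.69 (adjusted p = 0.000177). On log2 TPM with a pseudocount of 1 the median was −1.40, and that of cytokines −1.37. Cytokines and chemokines were lower in 22 of 33 and higher in 5 (22 and 5 adjusted over the list alone, median −2.17, adjusted p = 0.0106, adjusted p = 0.354 with an estimated correlation), with IL1B at −5.66 ± 0.99 (adjusted p = 0.00114). Markers of plasmacytoid and AXL dendritic cells were lower in 12 of 22 and higher in 4 (13 and 5 adjusted over the list alone, median −2.15, or −1.65 with low-count members at their bound, adjusted p = 0.0177, adjusted p = 0.222 with an estimated correlation). SIGLEC6 was at −7.88 ± 0.81 (adjusted p = 3.12e-05) and CLEC4C at 9.42 ± 0.96 (adjusted p = 2.95e-05). Aryl hydrocarbon receptor targets were lower in 6 of 10 and higher in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00631, adjusted p = 0.222 with an estimated correlation). Pattern recognition genes (21 of 39 lower, 9 higher, 22 and 9 adjusted over the list alone) and immediate-early and heat-shock genes (14 of 32 lower, 4 higher, 15 and 4 adjusted over the list alone) were both at adjusted p = 0.022, at adjusted p = 0.369 with an estimated correlation, and at 0.053 among nuclear protein-coding genes alone. Mitochondrially encoded mRNAs were lower in cDC1 in 8 of 13 (11 adjusted over the list alone, adjusted p = 0.00895, adjusted p = 0.379 with an estimated correlation), beside a mitochondrial share of 2.11% to 2.36% in OP9-feeder cDC1 and of 2.72% and 3.36% in cDC2, and this was lost without cDC2 replicate 2 (0.0596).

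Other lists were not called by camera between DLL1-feeder and OP9-feeder cDC1. Stress response genes of unfolded protein and amino acid supply went both ways, 7 of 29 higher and 5 lower (10 and 7 adjusted over the list alone, adjusted p = 0.988), with a median and mean above 0 and a camera direction below. DDIT3, a stress transcription factor, was higher by 2.29 ± 0.36 (adjusted p = 0.00311), and DDIT4 by 2.11 ± 0.41 (adjusted p = 0.00738). DC transcription factors were higher in 7 of 39 and lower in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.952), with BCL6 at 0.83 ± 0.17 (adjusted p = 0.0091) and CEBPA, a myeloid factor, at −1.50 ± 0.27 (adjusted p = 0.00509). Markers of plasmacytoid and AXL dendritic cells were lower in 5 of 22 and higher in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.0848), lymphoid markers lower in 5 of 15 (6 adjusted over the list alone, adjusted p = 0.219), and stem and progenitor markers lower in 4 of 18 (6 adjusted over the list alone, adjusted p = 0.119). Fry called each of these lists lower (adjusted p = 0.0274, 0.00697 and 0.0144). Langerhans cell markers (2 of 12 higher, 2 lower, 2 and 2 adjusted over the list alone, adjusted p = 0.219) and erythroid and megakaryocyte markers (1 of 8 higher, 2 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.402) were mixed. So were MHC class II presentation (3 of 21 higher, 3 lower, 3 and 4 adjusted over the list alone, adjusted p = 0.26) and integrins and adhesion (3 of 32 higher, 6 lower, 3 and 7 adjusted over the list alone, adjusted p = 0.469). On log2 TPM with a pseudocount of 1, medians changed sign for stem and progenitor (−0.07 to 0.03), erythroid (−0.22 to 0.27), MHC class II (−0.16 to 0.04), integrin (−0.05 to 0.11) and transcription factor (−0.06 to 0.11) genes.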
